A study of Bos taurus with 9 samples.

How the data were processed

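RNA from sorted bovine gamma delta T cells of 3 calves was labelled with biotin and hybridised to one-colour Affymetrix bovine arrays, 1 array per calf and condition, per the labels' protocols. The cells had been sorted to more than 97% purity, rested overnight and then stimulated for 4 h, and 15 µg of total RNA entered the labelling. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets. Its version, the software and any later step are not given in the sources used here.

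The deposited table holds 24128 probe sets by 9 arrays. Its values are linear ratios rather than the log2 values that the design had assumed before the data were examined: each probe set's median over the 9 deposited values is 1 to within 0.001, so the authors evidently divided each probe set by its own median. The scaling is thus read from the values, and no header or label states it. This division leaves differences between arrays intact and removes the signal level, so that dim and bright probe sets look alike and signal over background cannot be judged. It leaves log2 differences between arrays as they were. A variance prior that follows the mean level, tried as an alternative, does not follow brightness on such values. The array medians lay between 0.997 and 1. Log2 of the ratio was taken with no pseudocount, and 4 values, all in arrays of calf 304, stood at the lowest value of 0.01. The 112 Affymetrix control probe sets were left out of the tests. Scan dates were not analysed here. No pair of arrays was identical.

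Probe sets were named through the platform annotation, which can be old, updated by gene identifier through a RefSeq table. Of the tested probe sets, 13292 had 1 symbol, 86 had several and 10638 had none, and no gene was named from a probe set with several. For 2913 of the 9155 named genes more than 1 probe set existed, and the probe set with the highest mean over the 9 arrays stood for the gene. After the division by the median that rule no longer picks the brightest probe set. It favours probe sets that are high in a minority of the arrays, so it can raise the medians of lists and tilt their tests upward. Averaging the probe sets of each gene avoids that choice and was run beside it. Many members of the lists had no named probe set and were not analysed here, LY96 among them.

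Samples were grouped by their titles. Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default prior), one coefficient per group over all 9 arrays, with Benjamini-Hochberg adjustment at 0.05 over 24016 probe sets. The labels state no test, so the fit without a block was set as the main one before the data were examined. The fit with calf as a block was planned beside it. The titles give the same 3 calf numbers in each group, so the arrays are paired by animal. Deviations from the group means correlated at 0.62 to 0.833 in the 9 pairs of arrays from the same calf and at -0.648 to 0.198 in the 18 pairs from different calves. Verbs of change in the results refer to the fit that the sentence names. An SD beside a mean log2 change is that of the 3 within-calf differences.

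Named genes followed a rule set before the data were examined. It took up to 8 genes per direction and comparison among those past the threshold and of one direction in all 3 calves, first without and then with the block. Where fewer than 4 qualified it filled up to 4 by smallest unadjusted p. It added up to 4 members of each list with the largest changes, and a fixed set of cytokine, receptor and activation genes. JUNB, IER2, CRTAM in the direct contrast, the genes that passed adjusted over a list alone, the unnamed probe sets and the genes that differ between calves were named after their values were seen. The 21 lists were fixed beforehand: chemokines, cytokines, NF-kB targets and feedback, interferon-stimulated genes, LPS and pattern receptor signalling, early T cell activation, cytotoxic effector genes, markers of gamma delta T, alpha beta T, B, NK, monocyte and neutrophil, and platelet and erythrocyte cells, heat shock and unfolded protein response, oxidative and metal stress, apoptosis and survival, cell cycle, glycolysis, cholesterol synthesis, ribosomal proteins, and proteasome and antigen presentation. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated one. Changes are relative to all genes on the array, as RMA sets arrays to a common distribution.

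The procedure was tested on simulated data for Yamoa versus PBS, 10 runs of 24016 probe sets with 200 changed. With calf as a block it recovered 82.2% of probe sets changed by log2 0.5 and 99.4% of those changed by 1, and 5.26% of its calls were false. Without the block it recovered 24.2% and 80.8%. A list shifted by log2 0.5 was called in 10 of 10 runs by both fits, and of 200 tests of unshifted lists 6 with the block and 1 without it were called. The simulated probe sets varied independently of each other and responded alike in every calf. These rates therefore do not cover correlated genes or a calf that responds differently.

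Alternatives covered the block, calf as a random block, the variance prior, renormalization, restriction to 2 groups, a 2-fold minimum, 1 value per gene, and leaving out each calf and each array. The planned filter on mean level could not be run on values without a level, and a filter on the SD over arrays was used in its place.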

Results

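Transcript levels were measured in gamma delta T cells, a lymphocyte class that makes up a large part of the blood T cells of young cattle, after a short exposure to a plant extract or to a bacterial cell wall product. The cells were sorted by flow cytometry from the blood of 3 calves, numbered 301, 303 and 304. Each calf gave 1 culture for each of 3 conditions, which makes 9 one-colour Affymetrix arrays in 3 groups of 3. One group received phosphate-buffered saline (PBS), the vehicle. Another received an aqueous extract of Yamoa at 32.6 µg/ml, and the last received ultrapure lipopolysaccharide (uLPS), a TLR4 ligand, at 10 µg/ml, all for 4 h. The labels disagree on age, calling the donors neonatal in one place and 1 to 6 months old in another. Each value is a ratio of an array's signal to that probe set's median over the 9 arrays, so changes between arrays can be read but signal levels cannot. All 24016 probe sets other than array controls were tested, and 9155 genes could be named. Replicates were separate animals, and the number of arrays limits the precision.

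The first question was which transcripts Yamoa altered relative to the vehicle. With calf as a block, 31 probe sets rose, each in all 3 calves. With 3 calves, passing this fit favours changes of similar size in each calf. That agreement and the small SDs below therefore follow in part from the choice of probe sets. NR4A1, an immediate early nuclear receptor induced by T cell receptor signals, was 2.40-fold higher with Yamoa, a log2 change of 1.26 ± 0.13 (SD over calves, n = 3). Its relative NR4A2 was 2.21-fold higher (log2 1.15 ± 0.20). CRTAM, an adhesion receptor of activated lymphocytes, was 2.29-fold higher (log2 1.20 ± 0.20), and TNFRSF18, the costimulatory receptor GITR, was 2.23-fold higher (log2 1.16 ± 0.07). NFKBID, a nuclear inhibitor of NF-kB, was 2.01-fold higher (log2 1.01 ± 0.09).

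Smaller rises in the same fit were measured for RGS1, a regulator of G protein signalling (log2 0.90 ± 0.33), for the early activation marker CD69 (0.88 ± 0.19) and for the nucleoside transporter SLC29A1 (0.77 ± 0.16). IL2RA, the alpha chain of the interleukin 2 receptor, rose by 0.57 ± 0.04 on the same scale. In the fit with calf as a block, 32 of the 24016 probe sets passed limma's test at an adjusted p of 0.05, 31 of them higher and 1 lower. The 31 that rose did so in every calf, by log2 0.44 to 1.69 with a median of 0.69, and 21 carried a single gene symbol. Limma's adjusted p was 0.00448 for NR4A1, 0.0081 for NR4A2 and for TNFRSF18, 0.0108 for CD69 and 0.0327 for CRTAM. The strongest rise belonged to a probe set without a gene name (log2 1.69), and the probe set that fell is likewise unnamed. Of the other NR4A2 probe sets, the next largest change was log2 0.28, so the probe sets of this gene disagreed in size.

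Without the block, limma called 0 of the 24016 probe sets for Yamoa, while 1066 had an unadjusted p under 0.05 where 1200.8 would be due to chance. The lowest adjusted p was 0.0606. That fit counts differences between calves as error, which can push the number of small p below chance. With the block, 3216 had an unadjusted p under 0.05. The blocked calls numbered 7, all higher, without calf 304, and 0 without calf 301 or without calf 303.

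**Figure D1:**
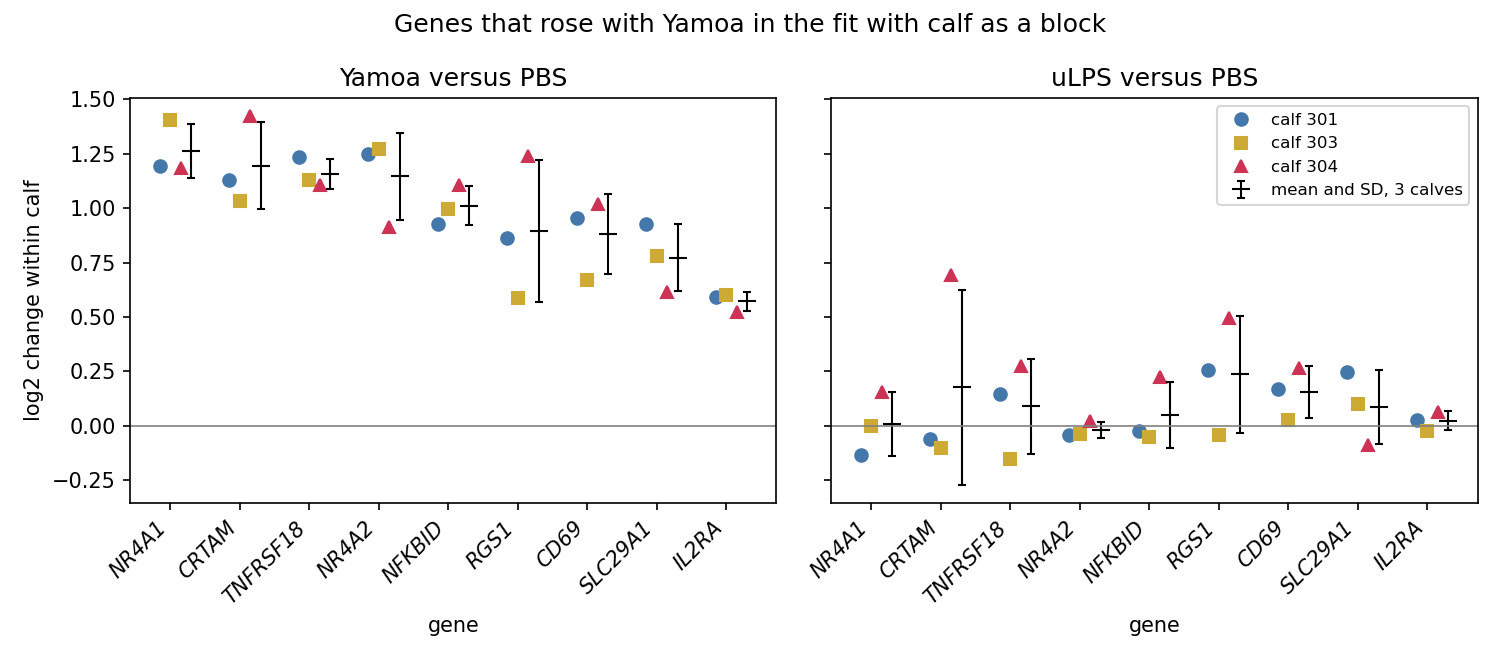
Log2 change within each calf (y axis) for 9 genes (x axis) that rose with Yamoa in the fit with calf as a block, for Yamoa minus PBS on the left and uLPS minus PBS on the right. Coloured symbols are the 3 calves and black bars the mean and SD. With Yamoa all 3 calves lie above 0 for each gene, from 1.26 on average for NR4A1 to 0.57 for IL2RA, and with uLPS the means lie between -0.02 and 0.24.

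Of the gene lists fixed beforehand, the NF-kB targets and feedback regulators had the highest median change with Yamoa, while the chemokine list had a higher mean (0.81 against 0.55). Of the NF-kB list's 25 measured members, 19 were higher in all 3 calves and 0 were lower in all 3, beside 19.8% and 14.5% of all named genes. The list median was 0.49 on the log2 scale, and 0.22, 0.36 and 0.78 in calves 301, 303 and 304. With the probe sets of each gene averaged, the median was 0.40 and 21 members were higher in all 3. GADD45B, a stress and NF-kB target, rose by log2 0.61 ± 0.05, and NFKB1, the p105 precursor, by 0.50 ± 0.05 with calf as a block. NFKB2, the p100 precursor, measured 1.22 ± 0.47 and NFKBIA, the inhibitor IkB alpha, 1.12 ± 0.42, and neither passed over all probe sets (limma adjusted p = 0.0665 and 0.0937 with the block). Adjusted over the list alone, 9 members passed without the block and 15 with it, all higher. Limma's camera test, which compares a list with all other genes, gave an adjusted p of 8.4e-16 for this list with a preset correlation of 0.01. The call was lost with an estimated correlation (adjusted p = 0.119).

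The early T cell activation list also rose with Yamoa. Its median over 24 members was log2 0.19, with 14 members higher in all 3 calves and 0 lower in all 3, and limma's camera gave an adjusted p of 2.51e-08. This call held with an estimated correlation (adjusted p = 0.012), although not when the block was added to it (adjusted p = 0.0517). Adjusted over the list alone, 6 members passed without the block and 11 with it, among them NR4A1, NR4A2, TNFRSF18, CD69, IL2RA and JUNB. Members of the heat shock and unfolded protein response list, chaperones and stress factors, had a median of 0.11 and a camera adjusted p of 0.000186, lost with an estimated correlation (adjusted p = 0.119). None of its 28 members passed alone, CALR measuring 0.33 ± 0.11 and HSPA5 0.21 ± 0.08. The interferon-stimulated genes lay slightly lower, with a median of -0.05 over 30 members, 12 lower and 4 higher in all 3 calves (camera adjusted p = 0.0453, and adjusted p = 0.668 with an estimated correlation). Without calf 301 the adjusted p of this list was 0.208, and without calf 303 it was 0.130. SAMD9 measured -0.23 ± 0.07 and GBP4 -0.23 ± 0.06 there, while ISG15 measured 0.59 ± 0.77.

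Several chemokine and cytokine genes differed widely between calves, while the cytokine list as a whole had medians of -0.01, 0.12 and 0.11 in calves 301, 303 and 304. In calf 304, the ratio of the Yamoa to the PBS culture was 149 for GRO1, a neutrophil-attracting chemokine, and 173 for CXCL2, while the same ratios were 1.16 and 1.09 in calf 301 and 1.82 and 1.51 in calf 303. IL1B measured 64.8-fold in calf 304 against 0.932 and 1.15 in the other calves, and IL6 measured 53.2-fold against 0.931 and 1.11. CXCL8, encoding interleukin 8, had ratios of 2.82 in calf 303 and 33.7 in calf 304, and a log2 change of 0.14 in calf 301. The means carried SDs larger than themselves, as for GRO1 (log2 2.77 ± 3.87) and IL6 (1.93 ± 3.30), and neither passed limma's test in either fit. TNF measured 0.61 ± 0.85, CSF2 0.59 ± 0.49, CCL20 0.37 ± 0.61 and IFNG 0.04 ± 0.05. At a 4-fold rise, 33 probe sets qualified with Yamoa in calf 304, 1 in calf 303 and 0 in calf 301.

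The cytokine list passed camera for Yamoa without the block (30 members, median 0.13, adjusted p = 0.0347), not with it (adjusted p = 0.0527, or 0.0422 with the probe sets of each gene averaged) and not with an estimated correlation (adjusted p = 0.119). Its adjusted p was 0.435 without calf 304 and 0.0596 without calf 303. The chemokine list (20 members, median 0.28) did not pass without the block (adjusted p = 0.0781), passed with it (adjusted p = 0.0194, and 0.00957 without calf 304) and had an adjusted p = 0.457 with the block and an estimated correlation. GRO1 and CXCL2, and likewise CCL3 and CCL4, are close copies of each other, so their probe sets may share signal. The 3 CCL3 probe sets gave 1.88, 0.95 and 0.018.

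**Figure D2:**
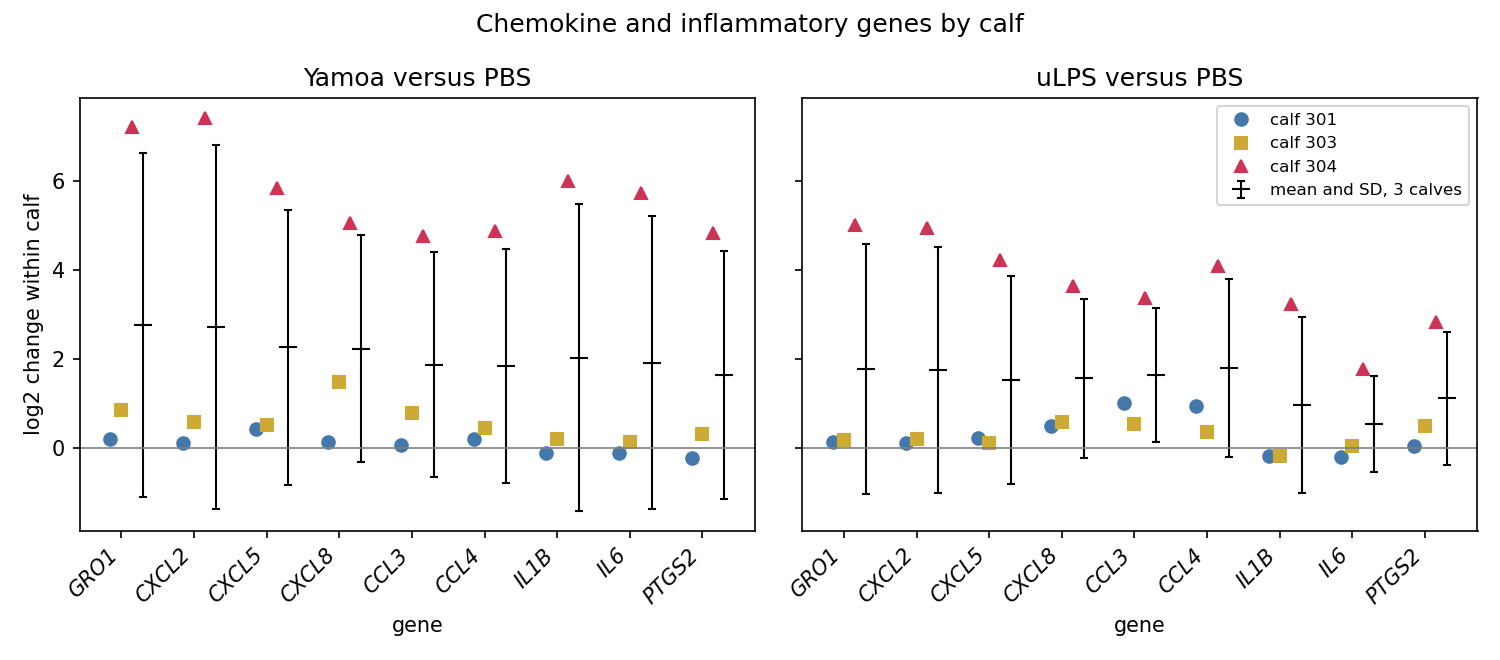
Log2 change within each calf (y axis) for 9 chemokine and inflammatory genes (x axis), for Yamoa minus PBS on the left and uLPS minus PBS on the right. Coloured symbols are the 3 calves and black bars the mean and SD. Calf 304 stands apart from the other calves for each gene, reaching 7.44 for CXCL2 with Yamoa and 5.02 for GRO1 with uLPS.

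Marker lists of other cell types were followed in every array, because the same calf also stood apart there. In the PBS cultures, monocyte and neutrophil markers were higher in calf 304 than in the mean of the other calves by a median of 1.64 on the log2 scale over 22 genes, a 3.11-fold difference. That median lay above all of 10000 random lists of that size. S100A12, a calcium-binding protein of granulocytes and monocytes, was 44.3-fold higher, the lectin FCN1 25.8-fold, the lysozyme gene LYZ2 21.8-fold and the LPS co-receptor CD14 9.86-fold. Of the 22 markers, 13 were at least 2-fold higher, while ITGAM, FCGR3A, MPO, CEBPA and CEBPB measured from 0.90-fold to 1.01-fold. B cell markers had a median difference of 0.88, with 3 of 7 at least 2-fold higher. Among them, MS4A1, encoding CD20, was 14.1-fold higher, while CD79A measured 0.92-fold and BLK 1.04-fold. The platelet chemokine PF4 was 5.62-fold higher, although its platelet and erythrocyte list differed by a median of -0.026. The NK cell, alpha beta T cell and gamma delta T cell lists differed by 0.058, -0.14 and -0.099. With Yamoa the monocyte and neutrophil, B, NK, alpha beta T and gamma delta T cell lists did not pass camera (adjusted p from 0.359 to 0.856). The monocyte and neutrophil list had a median of 0.088 and the B cell list one of -0.084.

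**Figure D3:**
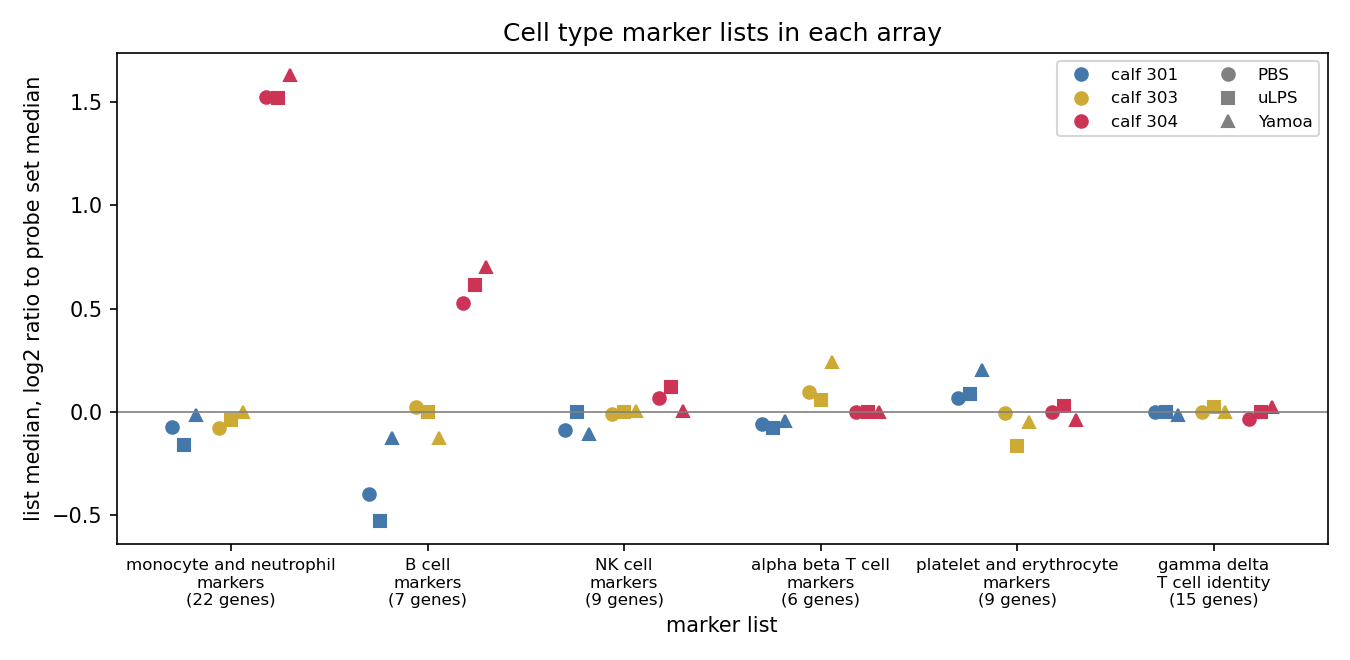
Median log2 ratio (y axis) of 6 cell type marker lists (x axis) in each of the 9 arrays, coloured by calf and with a symbol for each treatment. The monocyte and neutrophil list lies between 1.52 and 1.63 in the 3 arrays of calf 304 and between -0.16 and 0.0022 in the others.

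The remaining lists did not pass camera for Yamoa. Their medians and adjusted p were -0.013 and 0.437 for LPS and pattern receptor signalling, whose mean of 0.03 had the opposite sign, -0.015 and 0.963 for cytotoxic effector genes, and 0.1 and 0.23 for oxidative and metal stress. Apoptosis and survival genes gave 0.047 and 0.404, cell cycle genes 0.011 and 0.75, glycolysis genes 0.024 and 0.268, and cholesterol synthesis genes 0.062 and 0.359. Ribosomal proteins gave 0.017 and 0.444, proteasome and antigen presentation genes 0.035 and 0.845, and platelet and erythrocyte markers, with a mean of 0.013 against a test in the lower direction, an adjusted p of 0.963. Adjusted over the list alone and with the block, 4 of the 20 oxidative stress members were higher, the thioredoxin gene TXN (0.29 ± 0.11), its reductase TXNRD1 (0.33 ± 0.24), SQSTM1 (0.30 ± 0.03) and NFE2L2 (0.29 ± 0.18). In the same fit and adjustment, CXCL16 (1.07 ± 0.49), CEBPB (0.67 ± 0.25), BCL2L1 (0.42 ± 0.19), CD5 (0.41 ± 0.16) and BOLA-DQA1 (0.52 ± 0.14) were higher and IGHM (-0.28 ± 0.16) was lower, and none of these 10 genes passed without the block. Over all probe sets, no named gene passed on the lower side in either fit. CABYR (log2 -0.43 ± 0.16), the kinesin-associated KIFAP3 (-0.27 ± 0.08), the RNA-binding protein RBMX (-0.26 ± 0.05) and the kinesin KIF3C (-0.35 ± 0.14) had the smallest unadjusted p without the block among those lower in every calf, with 1 probe set per gene, and did not pass.

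The next comparison asked what uLPS did to the same cells. Several chemokine genes had their highest values in calf 304. CCL4 measured log2 0.95, 0.37 and 4.09 in calves 301, 303 and 304, CCL3 measured 1.01, 0.55 and 3.37, and GRO1 measured 0.14, 0.18 and 5.02 (mean 1.78 ± 2.80, SD, n = 3). IL1B had a mean of 0.97 ± 1.98 and IL6 one of 0.54 ± 1.08. ISG15, an interferon-induced ubiquitin-like protein, measured 0.43, 0.40 and 3.53, and the mitochondrial superoxide dismutase SOD2 had a mean of 0.79 ± 1.15. At a 4-fold rise, 21 probe sets qualified in calf 304, where monocyte and neutrophil markers were high already with PBS, and 0 in each of the other calves.

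In the early T cell activation list, CD69 measured 0.15 ± 0.12 with uLPS, IL2RA 0.023 ± 0.044, NR4A1 0.0074 ± 0.15 and the transcription factor gene JUNB 0.32 ± 0.15, with CD69 and JUNB higher in all 3 calves. None of these passed, and the early T cell activation list had a median of 0.057 (camera adjusted p = 0.183). The NF-kB list alone passed camera without the block, with a median of 0.12, 9 of 25 members higher in all 3 calves and an adjusted p of 0.00297. Its call was lost with an estimated correlation (adjusted p = 0.674) and without calf 304 (adjusted p = 0.683). NFKBIA measured 0.51 ± 0.60 and PTGS2, the inducible cyclooxygenase, 1.12 ± 1.49, and 0 members passed adjusted over the list alone. The chemokine list passed only with the block, with a median of 0.44 and 12 of 20 members higher in every calf (adjusted p = 0.00307, adjusted p = 0.0467 without calf 304, and adjusted p = 0.497 with the block and an estimated correlation). The other 19 lists did not pass in either fit, with medians from -0.096 to 0.06 and adjusted p from 0.172 to 0.78 without the block. The monocyte and neutrophil list (median -0.024) and the platelet and erythrocyte list (median -0.038) had medians below 0 and a test in the higher direction. LAT, an adaptor of T cell receptor signalling, was the 1 gene to pass adjusted over its list alone, with the block (0.33 ± 0.13).

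Limma called 0 probe sets for uLPS without the block, where 442 had an unadjusted p under 0.05, and 0 with the block, where 1742 did. The lowest adjusted p were 1.00 and 0.297. In the fit without the block and with 1 probe set per gene, those with the smallest unadjusted p among genes of one direction in all calves were KANSL3 (0.48 ± 0.22) and TAF6L (0.38 ± 0.14), both parts of chromatin-modifying complexes, and on the lower side APOA5 (-0.30 ± 0.11) and AMT (-0.30 ± 0.08). None of these passed.

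The direct contrast asked where the 2 stimuli differed. With calf as a block, Yamoa cultures had higher levels of NR4A1 (log2 1.25 ± 0.20, n = 3), NR4A2 (1.17 ± 0.24), TNFRSF18 (1.07 ± 0.23) and NFKBID (0.96 ± 0.08) than uLPS cultures. ID2, an inhibitor of helix-loop-helix transcription factors, was higher by 0.82 ± 0.06, CD69 by 0.73 ± 0.07, the granule exocytosis factor SYTL2 by 0.72 ± 0.05, SLC29A1 by 0.69 ± 0.01 and IL2RA by 0.55 ± 0.09. In this fit 19 probe sets passed at a limma adjusted p of 0.05, all higher with Yamoa, and 17 of them were among the 31 that rose with Yamoa against PBS. The adjusted p was 0.00602 for NR4A1 and for NFKBID, 0.00787 for NR4A2 and 0.028 for CD69. CRTAM, which rose against PBS, did not pass here (1.02 ± 0.25, adjusted p = 0.0838), though it did without calf 304 (1.16, adjusted p = 0.0189).

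The NF-kB list was higher with Yamoa than with uLPS, by a median of 0.31, or 0.22 with the probe sets of each gene averaged, with 17 of 25 members higher in all 3 calves (camera adjusted p = 1.07e-09, and adjusted p = 0.244 with an estimated correlation). NFKB2 measured 0.94 ± 0.35, NFKBIZ 0.74 ± 0.24 and BCL3 0.73 ± 0.34, and 6 members passed adjusted over the list alone without the block and 11 with it. The early T cell activation list was higher by a median of 0.13 (camera adjusted p = 2.08e-06, and adjusted p = 0.0248 with an estimated correlation). This call was lost with the block and an estimated correlation together (adjusted p = 0.0727). Interferon-stimulated genes were lower by a median of -0.1, with 12 of 30 members lower in all 3 calves (adjusted p = 3.43e-05, and adjusted p = 0.244 with an estimated correlation). ISG15 measured -0.27, -0.26 and -2.05 in calves 301, 303 and 304. Without calf 304 the adjusted p of the interferon list was 0.109, and 0.0193 with the block. The heat shock list was higher by 0.072 (adjusted p = 0.0111, and adjusted p = 0.244 with an estimated correlation), and did not pass without calf 301 (adjusted p = 0.0501), without calf 303 (adjusted p = 0.0839) or with the probe sets of each gene averaged (adjusted p = 0.136).

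With the block, the monocyte and neutrophil list was also higher (median 0.1) and the NK cell list lower (median -0.094), each at a camera adjusted p of 0.0299. Both had an adjusted p = 0.331 with the block and an estimated correlation, and without calf 304 the blocked adjusted p were 0.0756 and 0.124. No other list passed in this contrast, with adjusted p from 0.0962 to 0.9 without the block. LPS and pattern receptor genes (median 0.019), platelet and erythrocyte markers (median 0.01) and proteasome genes (median 0.001) had medians above 0 and a test in the lower direction, and apoptosis genes had a mean of 0.0085 with a median and test below 0. Without the block 0 probe sets passed, 691 had an unadjusted p under 0.05, against 2142 with the block, and the lowest adjusted p was 0.0561. The blocked calls numbered 6 without calf 304 and 0 without calf 301 or without calf 303. The fit without the block called 1 probe set, the unnamed one with the strongest rise against PBS, once calf 304 was left out. Inflammatory genes did not pass in this contrast either. IL6 measured 0.11, 0.10 and 3.96, IL1B 0.076, 0.37 and 2.76, and CXCL8 -0.35, 0.91 and 1.44 in calves 301, 303 and 304. On the lower side, C7H5orf24 (-0.55 ± 0.10), CRYBA2 (-0.39 ± 0.15), DNAL4 (-0.39 ± 0.21) and GFAP (-0.27 ± 0.10) had the smallest unadjusted p without the block, with 1 probe set per gene, and did not pass.

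The 2 responses were then compared as a whole. Across the 24016 probe sets, which are not independent replicates, the log2 changes with Yamoa and with uLPS had a Pearson r of 0.626. Unchanged groups sharing the same PBS arrays gave 0.5 on average and at most 0.586 in 100 simulated rounds. Those rounds drew each probe set independently and gave arrays no shared shift. Their maximum is therefore no limit for real arrays, whose probe sets can move together. The covariance was 0.0117 against a simulated 0.0059, a difference of 0.00581. Within calves, r was 0.507 for calf 301, 0.469 for calf 303 and 0.749 for calf 304. Without calf 304 the covariance was 0.00926, beside 0.00881 simulated for the means of 2 calves. Both simulations took their spread from the fit to all 3 calves, calf 304 included, which can raise their covariance. The simulation of 2 calves therefore cannot show whether an excess remained without calf 304. Because no uLPS call was made in either fit, 0 calls were shared and 0 were due with independent lists. With 3 PBS arrays the controls could not be split, and part of the excess may come from them. The 31 probe sets that rose with Yamoa had a median log2 change of 0.058 with uLPS, and 10 of them had an unadjusted p under 0.05 for uLPS, in either direction, in limma's fit with the block.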

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

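The filter on SD, the block joined to the robust prior or to averaged probe sets and some blocked list tests were chosen after the data were seen. The planned filter on mean level, alone and with the block, was not run, as the values hold no signal level, and for the same reason signal over background sets no limit that can be read here. Yamoa versus PBS had 0 calls without a block and 32 with the replicate block, 9 with calf as a random block, 6 with the block and a 2-fold minimum, 19 with the block and a robust trended prior, whose trend does not follow brightness here, 7 with the block without calf 304, 45 with the block among probe sets of above-median SD and 1 in that filter without the block. Yamoa versus uLPS had 0, and in that order 19, 6, 5, 15, 6, 20 and 1. Of the 32 and 19 blocked calls, 6 and 5 were among those made without calf 304. Leaving out a calf or a single array without the block gave 0 to 1 calls in both contrasts, and the 1 call was the unnamed probe set with the strongest rise with Yamoa, when the Yamoa array of calf 304 was left out in either contrast and when calf 304 was left out in Yamoa versus uLPS. With the block, leaving out calf 301 or 303 gave 0. uLPS versus PBS had 0 calls in every setting tried. Lists past camera's threshold for Yamoa versus PBS numbered 5, and 1 with an estimated correlation or 0 with that and the block. Leaving out calves gave 4 to 5. For uLPS versus PBS they numbered 1, and 2 with the block, 2 with the block and the probe sets of each gene averaged, 0 with an estimated correlation with or without the block, 2 with the block without calf 301 and 6 without calf 303. Leaving out calves without the block gave 1 to 5. For Yamoa versus uLPS they numbered 4, and 1 with an estimated correlation or 0 with that and the block. Leaving out calves gave 3 to 4. With the probe sets of each gene averaged, 5, 1 and 3 lists passed in the 3 contrasts in that order, the heat shock list being lost in Yamoa versus uLPS, and with the block added the oxidative stress list also passed for Yamoa versus PBS (adjusted p = 0.0453). The correlation of responses ran from 0.478 to 0.682 with a calf left out, and was 0.648 in the SD filter. Its lowest value came without calf 304 and was not above the 0.499 simulated on average for unchanged groups of 2 calves. For the log2 changes of 67 named results, 446 values under other settings kept direction and side of the threshold and 20 moved past it, all with the block, which changed no other gene's call. With uLPS and a calf left out, the log2 change ran from -0.17 to 1.54 for IL1B and from -0.081 to 0.91 for IL6, negative without calf 304, and from -0.033 to 0.15 for CSF2, negative without calf 303, the left-out calf having the highest value in each case. Of the list results, 74 kept their call and 36 lost it, 0 reversing. Where no cause is named, the cause was not tested.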

Other observations

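The calves differed from each other in far more probe sets than any stimulus changed. Of the 24016 probe sets, 5627 differed between calves at an adjusted p of 0.05 (limma, F test of calf in the blocked fit), and 130 of those spanned at least 4-fold between calf means. Each calf mean averages its PBS, uLPS and Yamoa cultures. A response of a single calf to the stimuli, as for CXCL2 in calf 304, thus also counts as a difference between calves. Genes are named here by size, after their values were seen. In calf 303, XIST, the noncoding RNA of X inactivation, was 72.8-fold above calf 301, and gamma chain receptor transcripts were higher, TARP 8.99-fold over calf 304, TRGC6 6.52-fold over calf 304 and TRGC4 5.95-fold over calf 301. CD8B was 5.14-fold higher and the receptor gene KIT 5.61-fold higher in calf 303 than in calf 301. The labels give no sex for the calves.

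In most of the 130, calf 304 was the calf that lay farther from the middle one, above it in 88 and below it in 11. The arrays of calf 304 differed from the rest in technical controls too. Hybridization control probe sets had median log2 ratios of 0.67, 0.48 and 0.79 in its PBS, uLPS and Yamoa arrays, and between -0.16 and 0.15 in the other 6 arrays. The difference between 3' and 5' control probe sets of eIF-4E was 0.90, 0.54 and 0.82 in calf 304 and at most 0.094 elsewhere. The other such controls differed less. Actin measured 0.12, -0.24 and 0.14 in calf 304 and from -0.11 to 0.15 elsewhere. GAPDH, EF1a and cyclophilin measured 0.11 to 0.34, 0.16 to 0.29 and 0.21 to 0.25 in calf 304. Elsewhere they were at most 0.061, 0.013 and 0.10. The adhesive glycoprotein THBS1 was 113-fold, the monocyte chemokine CCL2 50.7-fold and the scavenger receptor CD36 35-fold above calf 301. PRSS2, a trypsinogen gene, was at least 102-fold lower in calf 304 than in calf 301, with a value of calf 304 at the lowest the table holds, 0.01, and MAD2L1 16.4-fold and GSTO1 8.54-fold lower than in calf 303. One probe set of the class II gene BOLA-DQB1 was 33.7-fold lower in calf 301 than in calf 304, and another was 34.7-fold lower in calf 304 than in calf 301. These genes are polymorphic and have near copies, so hybridization of different alleles and level cannot be separated here.

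The following tests were chosen after the results were seen, except the splits of arrays. The first pattern is the probe sets that were 4-fold or more higher in calf 304 alone, 33 with Yamoa and 21 with uLPS. Of these, 15 and 14 belong to genes of the cytokine or chemokine lists, and 18 were shared. The 18 shared probe sets carried 12 gene symbols. Both changes were taken against the same single PBS array of calf 304, which favours shared probe sets. For those 18 the median log2 change in calf 304 was 5.13 with Yamoa and 3.50 with uLPS, and in calves 301 and 303 the medians lay between 0.14 and 0.27. An array-wide difference in hybridization between the arrays of calf 304 is argued against, since its hybridization controls changed by only -0.19 with uLPS and 0.12 with Yamoa. These controls do not cover the RNA of each culture. Monocytes left in the preparation are a candidate explanation, since their marker list was higher by log2 1.64 in the untreated culture of that calf, S100A12 by 44.3-fold and LYZ2 by 21.8-fold, although the sort should have removed them. Of the 22 listed markers 13 were at least 2-fold higher and 3 stand in another list too. How many of them gamma delta T cells express cannot be read from values without a level. Some B cell markers and PF4 were also higher, and a stronger response of this calf's own T cells remains open and untested.

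The next pattern is the rise of the early T cell activation list with Yamoa. Signals passed on from monocytes in the preparation of calf 304 are argued against as its cause, since the other calves' cells were in separate cultures and the list's median change was 0.18 in calves 301 and 303 as in calf 304, with 17 of 24 members higher in both of those calves and 1 lower in both. NR4A1, NR4A2 and TNFRSF18, 3 of the members, passed over all probe sets without calf 304 (limma with the block, adjusted p = 0.02, 0.0151 and 0.0409). As a list it passed camera without that calf at a preset correlation (adjusted p = 2.49e-07), not at an estimated one (adjusted p = 0.517), and the test by members was chosen after that p was seen. Monocytes in the other preparations stay open, as the values hold no level.

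The last pattern is the 31 probe sets that rose with Yamoa in the fit with calf as a block. LPS in the extract is argued against as the whole cause of this set, since its median change with uLPS was 0.058 beside 0.69 with Yamoa, and in calves 301, 303 and 304 it was 0.086, 0.0086 and 0.13 beside 0.71, 0.78 and 0.60. The probe sets were chosen by their change against the same PBS arrays, which raises both medians. The choice also favours high values in the Yamoa arrays, which raises the Yamoa median further and tilts the counts that follow. In the direct contrast with the block, 17 of the 31 passed. In 29 of the 31 the Yamoa culture was above the uLPS culture in all 3 calves, and in 24 the uLPS change was at most 0.25 times the Yamoa change. In 3, among them the immediate early gene IER2 (0.53 with uLPS, 0.44 with Yamoa), it was at least 0.5 times as large, so LPS stays open for single genes, and no biological explanation was tested.

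Each contrast of 3 against 3 arrays allows 10 splits, too few for a share under 0.05. With calf as a block, Yamoa versus PBS gave 32 calls in the real split and at most 0 in the others, so 1 of 10 splits gave as many. Yamoa versus uLPS gave 19 in the real split and at most 0 in the others, again 1 of 10. Only 4 of the 10 splits part all 3 pairs of arrays from a calf, as the real one does, and the other 3 of these also gave 0. For uLPS versus PBS with the block, and for all 3 contrasts without it, the real split gave 0 calls and the highest other split 0, so 10 of 10 splits gave as many.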
